A study of Mus musculus with 6 samples.

How the data were processed

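Polyadenylated RNA of mouse inguinal stromal-vascular cells was sequenced in 6 libraries, 3 with a control (puro) retrovirus and 3 with a Prdm16 retrovirus. Per the labels' protocols, RNA was extracted with Trizol and a PureLink kit, libraries were made with an Illumina TruSeq RNA kit, and cells grew in a standard medium; the labels record no adipogenic induction. The submitters' processing notes name STAR, featureCounts and Subread and the mouse genome build mm9, with no role or order, and their versions are not given in the sources used here. The values are whole-number counts per gene symbol as deposited by the authors, with no normalization, in a table of 24197 genes that holds the 6 libraries as its columns. The strand setting of the counting is not given in the sources used here, so reads of overlapping and antisense genes may be mixed. How reads shared between paralogs or pseudogenes were counted is not given either, so values of multigene families such as Oas, Ifit and the keratins are uncertain. The reference annotation used here was of another build, GRCm38.p6; it supplied the chromosome, the order along it and the transcript length and GC content of genes matched by symbol, and no positions are printed. A chromosome was found for 99.7% of the tested genes and length and GC content for 99.3%.

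Library totals ranged from 28169059 to 35798201 counts, and 3 counts, the floor used for a count of 0, stood for 0.0852 to 0.104 CPM in a library. The 100 most abundant genes took 14.4% to 14.6% of the counts in puro libraries and 11.6% to 11.7% in Prdm16 libraries. Replicate libraries of a group were compared by a chi-square of their counts per gene over genes with at least 10 counts. It gave 2.08 to 8.85 per gene, above the sampling noise of 1 in every pair. Repeat libraries of 1 culture could also exceed that noise, so this does not show independent replicates. Each library was counted as a replicate, as labelled. The common biological coefficient of variation was 4.78%.

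Groups and replicate numbers were taken from the sample labels. The groups, the test, the 28 gene lists with 688 genes, the rule for named genes and all but 2 of the alternatives were chosen before the data were examined. Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with the group, which left 13805 genes and removed 10392 that held 0.0297% of the counts. Libraries were scaled by TMM, and the groups were compared by a two-sided quasi-likelihood test with default settings and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. The SE of a log2 fold change was taken from the fold change and the F statistic. CPM values used the TMM-scaled library sizes. Where a group held 0 counts of a gene, its fold was bounded with 3 counts over that group, and where it held 1 to 3 counts the ratio was given with an exact 95% binomial counting interval.

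The lists covered brown and beige, general and white-selective adipocyte genes, fatty acid oxidation, ketone body metabolism, the TCA cycle and oxidative phosphorylation. They also covered extracellular matrix, contractile, TGF-beta and BMP, interferon, inflammatory, progenitor, Wnt and Hedgehog, and bone and cartilage genes. Markers of macrophages, endothelium, mammary epithelium, lymphocytes, Schwann cells, mesothelium, pericytes and skeletal muscle stood for other cells of the depot. The remaining lists were cell cycle, p53 targets, the unfolded protein and integrated stress response, cholesterol synthesis and immediate early genes. No gene was in more than 1 list. The 26 lists with at least 5 tested genes were tested two-sided with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and p-values were adjusted over the 26 lists. Members were also counted from edgeR p-values adjusted over the list alone.

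Named genes were 18 genes fixed in advance (among them Prdm16, Ucp1, Ppargc1a, Cidea, Pparg, Adipoq, Fabp4, Bdh1, Cpt1b, Ppara, Acta2, Col1a1, Tgfb1, Lep, Retn and Agt), the 8 largest increases and the 8 largest decreases, and from each list up to 4 members with the smallest edgeR p. The largest changes were taken among genes past the threshold whose groups did not overlap and whose mean was at least 5 CPM in the higher group, without predicted gene models and Prdm16. Other genes are marked as named after their values were seen. Some genes that the rule names are not reported here.

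Alternatives were RLE and upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, robust and newer edgeR fits, and a replicate block. Further ones were Prdm16 left out of the counts, an adjusted p of 0.01, a prior count of 0.5, camera on ranks, and leaving out each library in turn. The 2 chosen after seeing the data removed, through offsets, either the median log2 fold change of each gene's chromosome or a loess trend (span 0.5) on GC content and transcript length. Chromosome medians were bootstrapped over genes 1000 times and compared with 1000 random reassignments of genes to the 20 chromosomes (Y left out).

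The steps were tested on simulated data for this comparison, drawn from the puro means of 13805 genes and the real library sizes. In these data 200 genes of at least 1 CPM were changed, far fewer than differed in the real libraries. Scaling with most genes changed, and recovery of genes below 1 CPM, were therefore not tested. Of 50 genes per fold size the test recovered 70% at 1.25-fold, 90% at 1.5-fold and 100% at 2-fold and 4-fold, and it called 19 unchanged genes. A chromosome raised by 0.4 on the log2 scale was found at 0.397. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.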

Results

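Stromal-vascular cells are the fraction of adipose tissue that holds the adipocyte progenitors, fibroblasts, vascular cells and immune cells rather than the lipid-filled adipocytes. The libraries came from such cells of the inguinal fat depot of C57BL/6 mice, which had received either a control (puro) retrovirus or a retrovirus carrying Prdm16. Prdm16 is a zinc-finger transcriptional regulator known for its part in brown and beige fat cells, and the comparison asks what its forced expression does to the transcriptome of these cells. Each group had 3 libraries. The puro libraries held 31866630, 35798201 and 34303737 counts and the Prdm16 libraries 34349660, 28169059 and 32678897, so that 3 counts, the floor that a count of 0 allows, stood for 0.0852 to 0.104 CPM in a library, where CPM is the count scaled to the library total after TMM adjustment. The labels do not say that the replicates came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. CPM values are given as mean ± SD with n = 3, log2 fold changes as Prdm16 over puro ± SE, and the adjusted p of a gene is that of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13805 genes.

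Prdm16 itself was read from 14, 22 and 25 counts in the puro libraries and from 98437, 72525 and 89054 in the Prdm16 libraries. Its level rose from 0.609 ± 0.148 to 2656 ± 146 CPM (SD, n = 3), a log2 fold change of 12.07 ± 0.09 (adjusted p = 4.54e-14). The gene took 0.257% to 0.287% of the counts of the Prdm16 libraries. Reads of the delivered and of the endogenous gene could not be separated in a table of counts per gene.

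Of the 13805 genes tested, 5178 were higher and 5252 lower in the Prdm16 libraries at an adjusted p below 0.05, together 10430 genes or 75.6%. TMM scaling centres the fold changes (median −0.01), so the balance of higher and lower genes depends on it, and upper-quartile scaling gave 5011 higher and 5415 lower. A log2 change of at least 1 in size was reached by 3015 of them, 1338 higher and 1677 lower. The groups did not overlap for 10712 genes (77.6%), against 10% by chance with 3 against 3. Libraries of the same group had a Pearson r of 0.996 to 0.997 in log2 CPM across genes and libraries of different groups 0.892 to 0.895. The first principal component held 95.7% of the variance and separated the groups.

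The genes with the largest rises were nearly silent in the puro libraries. Mpzl2, an adhesion protein of epithelia, had 1 count over the puro group and 70.2 ± 2.03 CPM in the Prdm16 libraries (SD, n = 3), a ratio of 6966 with an exact 95% counting interval of 1250 to 275160. Lsr, a protein of tricellular epithelial junctions, and Lrrtm1, a synaptic membrane protein, had 3 counts each over the puro group and ratios of 2122 (726 to 10293) and 2186 (748 to 10602). Against a floor of 3 counts over the puro group, which held no count of them, the ETS transcription factor Erg was at least 325-fold higher and the ion transport regulator Fxyd3 at least 323-fold. The same floor put the steroid 21-hydroxylase Cyp21a1 at least 317-fold higher, the glutamate receptor subunit Gria4 at least 286-fold and the endophilin Sh3gl2 at least 251-fold. The few puro counts lay in 1 library each for Mpzl2 and Lsr and in 2 for Lrrtm1, and the fitted log2 fold change moved from 12.30 to 14.18 for Mpzl2 and from 10.92 to 11.80 for Lrrtm1 without puro replicate 1, and from 10.88 to 14.02 for Lsr without puro replicate 2. Cyp21a1 has a near-identical pseudogene copy, so its count is uncertain. Intervals and floors cover counting error only.

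The genes with the largest falls included the transcription factor Sox11, at 5.20 ± 0.160 CPM in the puro libraries (SD, n = 3) and 0 counts in the Prdm16 libraries, at least 169-fold lower over the group. Gpr149, an orphan receptor, fell from 760 counts to 1, a ratio of 745 with a counting interval of 133 to 29481. Megf10, an engulfment receptor, and Rxfp1, the relaxin receptor, fell, with log2 fold changes of −8.78 ± 0.16 and −8.23 ± 0.37. The potassium channel Kcnc2 had a log2 fold change of −7.63 ± 0.21, the G-protein regulator Rgs17 of −7.56 ± 0.28, the troponin Tnnt2 of −7.00 ± 0.23 and Slfn2 of −6.96 ± 0.13. Without Prdm16 replicate 2, which held 4 of its 5 counts there, Rgs17 had −9.15, and without Prdm16 replicate 1 −6.94, and the fitted value of Gpr149 moved from −9.09 to −10.96 without Prdm16 replicate 3. The largest adjusted p among these 16 genes was 1.07e-08.

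Genes of brown and beige adipocytes went both ways. Of 20 tested members 10 rose, 8 fell and 2 did not pass, and the counts adjusted over the list alone were the same. A further 12, among them Dio2, Cox8b and Elovl3, were too low to be tested, with at most 26 counts over a group. Ppargc1a, the coactivator of mitochondrial biogenesis, rose from 6.65 ± 0.575 to 107 ± 7.56 CPM (SD, n = 3; log2 fold change 4.01 ± 0.07, adjusted p = 3.70e-12), and the fatty acid elongase Elovl6 rose by 1.87 ± 0.08. Ebf2, a transcription factor of brown preadipocytes, fell by 2.61 ± 0.05 on the log2 scale, and Tbx15 had a log2 fold change of −0.98 ± 0.04. The uncoupling protein Ucp1 was too low to be tested, with 1 count over the puro group and 14 over the Prdm16 group, a ratio of 14.3 with a counting interval of 2.17 to 604. Cidea, also untested, had 2 and 7 counts, a ratio of 3.57 (0.679 to 35.2). The camera test of the list, which sets its members against all other tested genes, gave an adjusted p of 0.654.

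General adipocyte genes rose more often than they fell, with 20 higher, 9 lower and 3 not passing among 32 tested, and the same counts adjusted over the list alone. A further 6, among them Plin1, Pck1 and Adrb3, were too low to be tested, with at most 17 counts over a group. Fabp4, the fatty acid binding protein of adipocytes, rose from 115 ± 10.1 to 551 ± 51.3 CPM (SD, n = 3; log2 fold change 2.26 ± 0.08, adjusted p = 3.30e-10). The insulin-responsive glucose transporter Slc2a4 rose by 5.04 ± 0.16, the fatty acid transporter Cd36 by 4.36 ± 0.10, Adipoq by 3.05 ± 0.21 from 28 counts over the puro group, and Pparg, the nuclear receptor that drives adipogenesis, by 0.46 ± 0.04. Lipoprotein lipase, Lpl, went the other way, from 940 ± 33.3 to 159 ± 2.19 CPM (SD, n = 3; log2 fold change −2.57 ± 0.04). The list was higher by camera (median log2 fold change 0.68, adjusted p = 0.0324), with adjusted p = 0.31 with an estimated correlation between genes. Genes selective for white adipocytes were lower for 9 of 13 tested, higher for 3 and not passing for 1, equal to the counts adjusted over the list alone. Among the fallen genes Nnmt, a nicotinamide methyltransferase, had a log2 fold change of −4.42 ± 0.11, angiotensinogen, Agt, of −3.20 ± 0.09, the matrix protein Dpt of −2.79 ± 0.08 and the positional regulator Hoxc8 of −1.64 ± 0.04. The 3 that rose, named after their values were seen, were Psat1 (1.04 ± 0.06), Rb1 (1.02 ± 0.06) and Nrip1 (0.27 ± 0.05). This list was lower by camera (median −0.90, adjusted p = 0.0324) and had adjusted p = 0.31 with an estimated correlation. Its call ended when the median of each chromosome was removed (adjusted p = 0.0586, an alternative chosen after seeing the data) and without a filter on low counts (0.0931). Lep, the satiety hormone of fat, had 0 counts over the puro and 5 over the Prdm16 group, and Retn 1 and 2, all too low for a test.

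**Figure D1:**
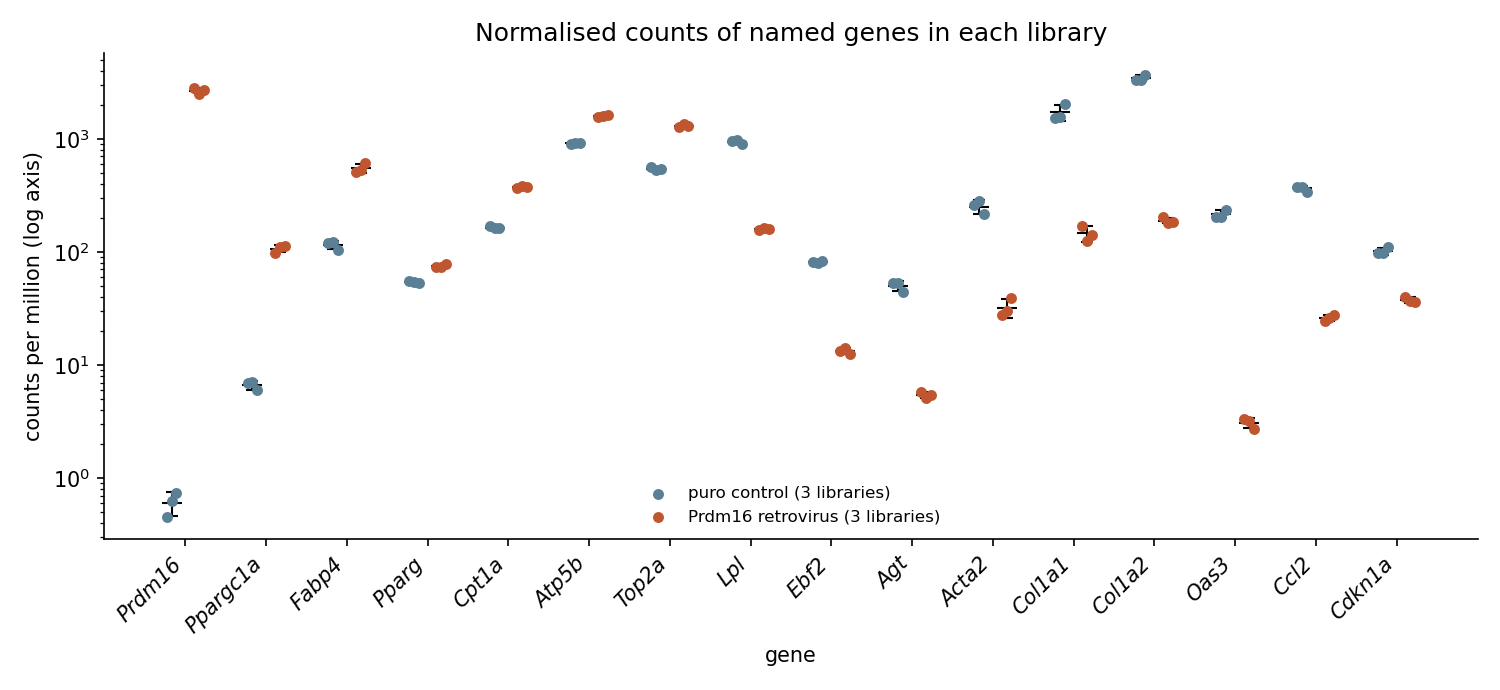
Normalised count in CPM (log axis) of 16 named genes in each of the 3 puro and 3 Prdm16 libraries, with the group mean as a bar and the SD as error bar. Prdm16, Ppargc1a and Fabp4 lie higher in all Prdm16 libraries, and Lpl, Ebf2, Col1a2 and Oas3 lower, with spreads within a group far smaller than the distance between groups.

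Mitochondrial oxidation genes rose by small amounts in most members. In the TCA cycle list 21 of 23 rose, none fell and 2 did not pass, and 22 rose when adjusted over the list alone. The isocitrate dehydrogenase subunit Idh3a rose by 1.21 ± 0.04 on the log2 scale, the pyruvate dehydrogenase subunit Pdhb by 1.06 ± 0.04, Suclg1 by 1.03 ± 0.04 and Idh2 by 0.76 ± 0.03. With the median of each chromosome removed, Pdhb had 0.57. Camera called the list higher (median 0.62, adjusted p = 1.23e-06), with adjusted p = 0.31 with an estimated correlation. Among 72 genes of oxidative phosphorylation 56 rose, 8 fell and 8 did not pass, with 58 higher and 8 lower adjusted over the list alone. The ATP synthase subunit Atp5b rose from 913 ± 10.4 to 1595 ± 35.1 CPM (SD, n = 3; log2 fold change 0.80 ± 0.03), the complex I subunit Ndufv1 by 0.93 ± 0.04, and the cytochrome oxidase subunit Cox5a by 0.75 ± 0.04. Ndufv1 had 0.53 with chromosome medians removed. The list was higher by camera (median 0.36, adjusted p = 1.45e-05), with adjusted p = 0.466 with an estimated correlation.

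Fatty acid oxidation had 18 higher, 7 lower and 4 not passing among 29 genes, and the same counts adjusted over the list alone. Cpt1a, which admits fatty acids to mitochondria, rose by 1.18 ± 0.03 on the log2 scale, the dehydrogenase Hadh by 1.03 ± 0.04, and Acadl and Hadhb were 2.38-fold and 2.15-fold higher. The muscle form Cpt1b had a log2 fold change of 0.12 ± 0.11 (adjusted p = 0.301), and of 0.50 with an adjusted p of 0.00137 once the median of each chromosome was removed, which also moved Cpt1a to 0.79 and Ppara to 0.93. Ppara, a nuclear receptor of fatty acid oxidation, had 0.55 ± 0.19 (adjusted p = 0.0196). Its call was lost without puro replicate 1 (0.48), puro replicate 3 (0.43) or Prdm16 replicate 2 (0.47). The list was higher by camera (median 0.31, adjusted p = 0.0324), with adjusted p = 0.398 with an estimated correlation. Ketone body genes rose for 7 and fell for 3 of 10, as they did adjusted over the list alone, and camera did not call the list (median 0.45, adjusted p = 0.152). The ketone body dehydrogenase Bdh1 went from 2 to 110 counts, a ratio of 56.1 with a counting interval of 15.2 to 469 (fitted log2 fold change 5.57, and 8.21 without puro replicate 3, which held both counts), while Bdh2, a cytosolic dehydrogenase, fell by 2.36 ± 0.08. Acat1 rose by 0.97 ± 0.03 and Aacs by 0.88 ± 0.05. The ketone list was called with a filter of at least 1 CPM in at least 3 libraries (adjusted p = 0.0398), and had adjusted p = 0.343 with the usual filter and an estimated correlation.

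Extracellular matrix genes fell in most members: 33 of 39 were lower, 5 higher and 1 not passing, and so they were adjusted over the list alone. The collagen I chains Col1a2 and Col1a1 fell, with log2 fold changes of −4.18 ± 0.06 and −3.55 ± 0.13, the latter from 1705 ± 284 to 145 ± 22.6 CPM (SD, n = 3; adjusted p = 7.26e-10). The matricellular proteins Thbs2 and Postn fell, at −4.41 ± 0.05 and −3.85 ± 0.05, as did the collagen cross-linking enzyme Lox, at −2.90 ± 0.04. The 5 that rose, named after their values were seen, were Eln (3.86 ± 0.16), Lum (2.64 ± 0.45), Col15a1 (2.27 ± 0.19), Spp1 (0.76 ± 0.07) and Col5a3 (0.43 ± 0.11). The list was lower by camera (median −0.95, adjusted p = 6.59e-08), with adjusted p = 0.31 with an estimated correlation. Of 16 contractile genes of myofibroblasts and smooth muscle 12 fell and 4 rose, as they did adjusted over the list alone. Smooth muscle actin, Acta2, fell from 251 ± 33.7 to 32.1 ± 5.89 CPM (SD, n = 3; log2 fold change −2.97 ± 0.12), with Tagln at −3.77 ± 0.12, Myl9 at −2.42 ± 0.08 and Tpm2 at −1.74 ± 0.05. The 4 that rose, named after their values were seen, were Vcl (0.56 ± 0.04), Mylk (0.30 ± 0.04), Smtn (0.20 ± 0.08) and Flna (0.12 ± 0.04). Camera gave an adjusted p of 0.0324 for this list (median −0.55), with adjusted p = 0.343 with an estimated correlation.

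TGF-beta and BMP signalling genes were mixed, with 9 higher, 14 lower and 4 not passing among 27 and the same counts adjusted over the list alone. The TGF-beta targets Ltbp2 and Tgfbi fell, with log2 fold changes of −3.59 ± 0.09 and −3.08 ± 0.04, and the receptor Tgfbr2 rose by 1.39 ± 0.03. The ligand Tgfb1 had a log2 fold change of −0.20 ± 0.11 (adjusted p = 0.125), which passed without puro replicate 2 (−0.28). The list was not called by camera (median −0.27, adjusted p = 0.316).

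Interferon response genes fell almost throughout: 42 of 43 were lower and 1 was higher, and so they were adjusted over the list alone. Oas3, a sensor of double-stranded RNA, fell from 215 ± 17.4 to 3.10 ± 0.329 CPM (SD, n = 3; log2 fold change −6.12 ± 0.09, adjusted p = 7.32e-13). Ifi44 fell with a log2 fold change of −3.41 ± 0.04, Ifit3 with −2.96 ± 0.04 and Oas1a with −2.81 ± 0.04. The member that rose was Ifi27 (1.33 ± 0.04), named after its values were seen. Camera called the list lower (median −1.70, adjusted p = 8.09e-15), with adjusted p = 0.31 with an estimated correlation. Members of the Oas and Ifit families share sequence, so their single values are uncertain. Inflammatory cytokines and NF-kappaB targets were lower for 13, higher for 7 and not passing for 3 of 23, equally so adjusted over the list alone, and were not called by camera (median −0.29, adjusted p = 0.131). The chemokines Ccl7, Ccl2 and Cxcl12 fell, with log2 fold changes of −4.97 ± 0.06, −3.80 ± 0.06 and −2.84 ± 0.05. Complement C3 rose from 404 ± 10.2 to 1684 ± 29.5 CPM (SD, n = 3; log2 fold change 2.06 ± 0.04).

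Adipocyte progenitor markers were lower for 13, higher for 6 and not passing for 1 of 20, also adjusted over the list alone, and camera did not call the list (median −0.92, adjusted p = 0.152). F3, which marks a progenitor subset, fell by 3.16 ± 0.04 on the log2 scale and Pdgfrb was 2.84-fold lower, whereas the early progenitor marker Cd24a rose by 4.68 ± 0.07 and Gata2, a repressor of adipogenesis, by 3.56 ± 0.08. Wnt and Hedgehog genes divided into 10 higher, 10 lower and 1 not passing, also adjusted over the list alone. Wnt5b rose by 7.16 ± 0.17 from 13 counts over the puro group, and the receptor Fzd4 by 1.99 ± 0.05, while the Wnt modulator Sfrp4 fell, at −3.74 ± 0.06, and so did the Wnt target Wisp1, at −1.98 ± 0.06. The list's median was −0.06 and its mean 0.10, and camera put it lower with an adjusted p of 0.986. Bone and cartilage genes were higher for 3, lower for 6 and not passing for 1 of 10, with the same counts adjusted over the list alone (median −0.66, camera adjusted p = 0.351). The matrilin Matn2 and the chondrogenic factor Sox9 fell, at −2.92 ± 0.04 and −2.26 ± 0.09, and Col11a1 and Mgp rose by 1.68 ± 0.07 and 1.08 ± 0.08.

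**Figure D2:**
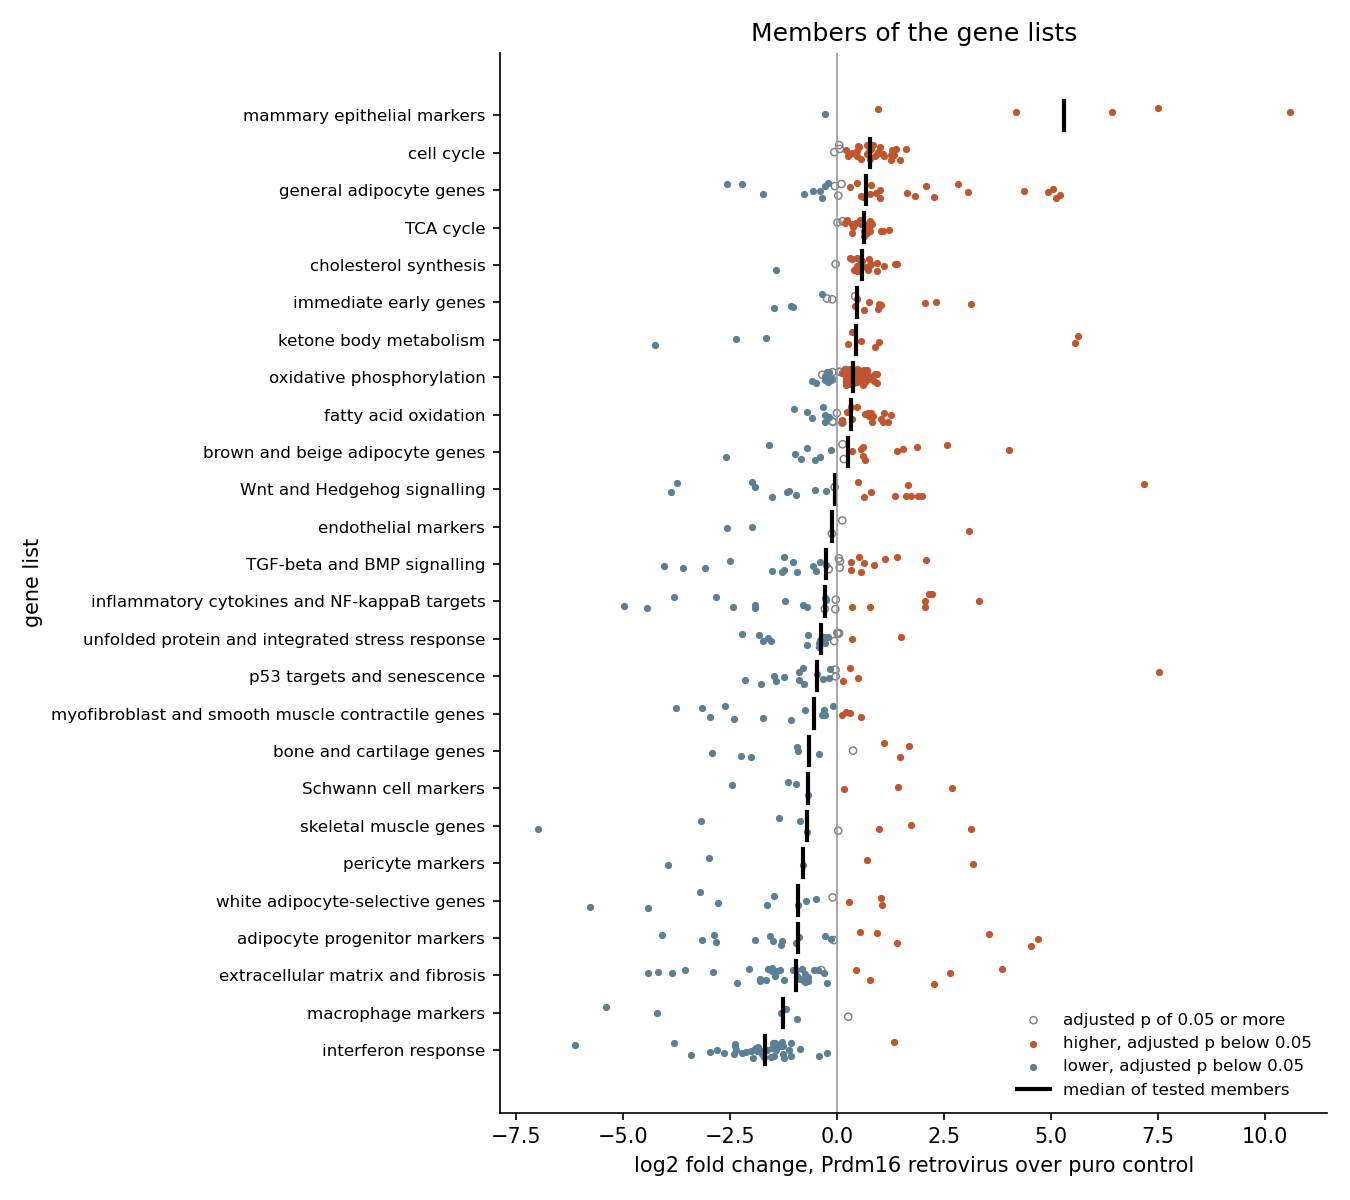
Log2 fold change (Prdm16 over puro) of each tested member of the 26 gene lists with at least 5 tested genes, sorted by the median (black bar). Filled points passed an adjusted p of 0.05, and the value of Esrp1, farthest to the right, is a fitted one for a gene with 0 puro counts. The interferon and extracellular matrix lists lie mostly to the left of 0, and the cell cycle and TCA cycle lists to the right.

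Markers of mammary epithelium, a tissue embedded in the inguinal depot, rose for 5 and fell for 1 of 6 tested, also adjusted over the list alone. Krt18, a keratin of simple epithelia, rose from 7 counts over the puro group to 1304 (13.3 ± 0.681 CPM, SD, n = 3; log2 fold change 7.49 ± 0.24), and E-cadherin, Cdh1, by 6.42 ± 0.20. The epithelial splicing regulator Esrp1 was at least 193-fold higher against the floor of 3 counts over the puro group, and Epcam rose by 4.18 ± 0.47. Without puro replicate 3, which held 5 of the 6 puro counts of Epcam, its value was 5.93, and without puro replicate 2 it was 3.58; that of Krt18 was 8.08 without puro replicate 3. Keratins have related pseudogene copies, which makes the count of Krt18 uncertain. The remaining 10 members were too low to be tested, with at most 37 counts over a group. Camera called the list higher (median 5.30, also with Esrp1 at its bound; adjusted p = 0.0422), with adjusted p = 0.31 with an estimated correlation. The call was lost without puro replicate 1 (adjusted p = 0.0859), Prdm16 replicate 1 (0.126), 2 (0.133) or 3 (0.114), with a prior count of 0.5 (0.0593) and without a low-count filter (0.346).

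Of mesothelial markers 2 rose, Msln by 3.86 ± 0.05 and Krt19 by 6.11 ± 0.21 on the log2 scale, and Wt1 fell from 75 counts to 1, a ratio of 73.6 with a counting interval of 12.8 to 2944 (fitted log2 fold change −5.75, and −7.63 without Prdm16 replicate 3). The same counts held adjusted over the list alone, and 3 tested genes were too few for a set test. Another 6 mesothelial markers were too low to be tested, with at most 28 counts over a group. Macrophage markers fell for 5 of 6 tested and 1 did not pass, with 5 lower and 1 higher adjusted over the list alone. A further 13 were too low to be tested, with at most 31 counts over a group, and C1qa, C1qb, C1qc and Tyrobp had 0 counts. Lyz2 went from 146 counts to 3 over the group, a ratio of 47.7 (16.01 to 234), and Ctss from 63 to 3, a ratio of 20.6 (6.73 to 103). Their fitted log2 fold changes, −5.41 and −4.21, moved to −4.82 and −5.00 without Prdm16 replicate 1, and that of Lyz2 to −6.33 without Prdm16 replicate 2. Cd74 and Cd14 had log2 fold changes of −1.21 ± 0.07 and −1.31 ± 0.09, and Cd74 had −0.80 with chromosome medians removed. The camera test gave an adjusted p of 0.051 (median −1.26), and adjusted p = 0.31 with an estimated correlation. It was below 0.05 without puro replicate 1 (0.0313) and without Prdm16 replicate 1 (0.0424), 2 (0.0496) or 3 (0.0421) and on ranks (0.0341). Of the lymphocyte markers 1 was tested, Lck, at −1.14 ± 0.16 (adjusted p = 5.34e-05 over all genes, and lower also adjusted over the list alone), and the other 13 had at most 9 counts over a group.

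Endothelial markers were higher for 1, lower for 2 and not passing for 2 of 5, also adjusted over the list alone (median −0.13, camera adjusted p = 0.784). A further 11 were too low to be tested, with at most 33 counts over a group, and Cdh5, Cldn5, Robo4 and Sox17 had 0 counts. Tek, the angiopoietin receptor, rose by 3.08 ± 0.15 on the log2 scale, Vwf and Eng fell, at −2.57 ± 0.22 and −1.99 ± 0.24, and Egfl7 had a log2 fold change of 0.12 ± 0.08 (adjusted p = 0.19). Of 5 pericyte markers 2 rose, Mcam by 3.16 ± 0.05 and Notch3 by 0.69 ± 0.06, and 3 fell, among them Cspg4 and Rgs5 at −3.95 ± 0.13 and −2.99 ± 0.68, with the same counts adjusted over the list alone. Pericyte markers too low to be tested numbered 4, with at most 17 counts over a group. The 5 counts of Rgs5 in the Prdm16 group all lay in replicate 3, without which its log2 fold change was −6.83, and it was −2.37 without Prdm16 replicate 1. The pericyte median was −0.79 and camera put the list lower (adjusted p = 0.983), while fry, which asks whether the members move on balance one way, put it higher (adjusted p = 2.39e-05), and camera with an estimated correlation put it lower (adjusted p = 0.986). Schwann cell markers rose for 3 and fell for 4 of 7, also adjusted over the list alone (median −0.67, camera adjusted p = 0.668). Among them Erbb3 rose by 2.69 ± 0.10, and Mbp and S100b fell, at −2.46 ± 0.18 and −1.15 ± 0.13. The 3 untested ones, Sox10, Foxd3 and Gfra3, had 0 counts. Skeletal muscle genes were higher for 3, lower for 5 and not passing for 1 of 9, also adjusted over the list alone (median −0.70, camera adjusted p = 0.458), with 22 more too low to be tested. Besides Tnnt2, Neb and Pax3 fell, at −3.18 ± 0.23 and −0.70 ± 0.04, and Tnnc1 rose by 1.71 ± 0.11.

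Cell cycle genes rose for 30 of 33 tested and 3 did not pass, also adjusted over the list alone. The mitotic kinesin Kif11 rose by 1.60 ± 0.04 on the log2 scale, cyclins Ccnb1 and Ccna2 were 2.37-fold and 2.14-fold higher, and the topoisomerase Top2a rose from 542 ± 15.8 to 1297 ± 35.6 CPM (SD, n = 3; log2 fold change 1.26 ± 0.04). The list was higher by camera (median 0.78, adjusted p = 4.86e-09), with adjusted p = 0.16 with an estimated correlation. Targets of p53 were lower for 13, higher for 4 and not passing for 2 of 19, also adjusted over the list alone. The cyclin-dependent kinase inhibitor Cdkn1a and the receptor Eda2r fell, at −1.43 ± 0.06 and −2.16 ± 0.06, and Plk2 was 2.37-fold lower. Perp, which is also a desmosomal protein of epithelia, rose by 7.51 ± 0.12, as did, named after their values were seen, Sesn1 (0.49 ± 0.07), Btg2 (0.29 ± 0.04) and Ei24 (0.15 ± 0.04). The camera call of this list (lower, median −0.48, adjusted p = 0.0435, and adjusted p = 0.434 with an estimated correlation) was lost without Prdm16 replicate 1 (0.053) or 3 (0.0543). It was also lost with chromosome medians removed (0.0726).

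Genes of the unfolded protein and integrated stress response were lower for 14, higher for 2 and not passing for 4 of 20, also adjusted over the list alone. The asparagine synthetase Asns fell by 1.72 ± 0.04 on the log2 scale, and the transcription factors Ddit3 and Atf4 had log2 fold changes of −1.55 ± 0.05 and −0.68 ± 0.03, that of Atf4 becoming −0.30 with chromosome medians removed. The lipoprotein receptor Vldlr rose by 1.48 ± 0.06, and Dnajc3, named after its values were seen, by 0.35 ± 0.04. The list was lower by camera (median −0.37, adjusted p = 0.00885), with adjusted p = 0.31 with an estimated correlation. Cholesterol synthesis genes rose for 19, fell for 1 and did not pass for 1 of 21, also adjusted over the list alone. Fdft1, the squalene synthase, rose by 1.40 ± 0.08 (0.90 with chromosome medians removed), while the sterol isomerase Ebp fell by 1.43 ± 0.06. Camera gave an adjusted p of 0.000974 (higher, median 0.57), with adjusted p = 0.425 with an estimated correlation. Immediate early genes were higher for 10, lower for 4 and not passing for 3 of 17, also adjusted over the list alone, and were not called by camera (median 0.46, adjusted p = 0.189). The nuclear receptors Nr4a1 and Nr4a2 rose by 3.13 ± 0.07 and 2.31 ± 0.12 and Egr3 by 2.05 ± 0.13, and Myc fell by 1.08 ± 0.08, with a log2 fold change of −0.71 once chromosome medians were removed.

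Of the 26 lists tested, 13 passed camera's preset correlation, 7 higher and 6 lower. With a correlation estimated from the libraries camera called 0 of the 26, with 3 at an unadjusted p below 0.05, and fry called 25. The estimate was 0.283 for the TCA cycle list, but −0.0141 for white-selective and −0.0063 for stress response genes, below the preset 0.01. For these 2 lists the unadjusted camera p still rose, from 0.0134 to 0.059 and from 0.00238 to 0.0295. A higher correlation between genes therefore does not account for the loss of these 2 calls. The count of 0 of the 26 cannot be put down to correlation between genes alone.

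Genes of whole chromosomes differed between the groups, relative to the median of all tested genes. The median log2 fold change was 0.49 for the 445 tested genes of chromosome 14 (95% bootstrap interval over genes 0.45 to 0.52) and 0.40 for the 502 of chromosome 19 (0.36 to 0.47). It was −0.40 for the 396 genes of chromosome 18 (−0.47 to −0.32) and −0.37 for the 579 of chromosome 15 (−0.42 to −0.33). On chromosome 14 83.8% of genes lay above 0 and on chromosome 18 24.5%. Chromosomes 3, 16, 8 and 5 had smaller medians of −0.19, −0.15, 0.13 and 0.19, also beyond 0.115, the largest of 1000 random reassignments of genes, and the other 12 lay between −0.10 and 0.05. Libraries of the same group differed by at most 0.0616 in the median of any of chromosomes 14, 15, 18 and 19. Of the genes on these 4 chromosomes 85.1% passed the test, against 74.0% elsewhere. With the median of each chromosome removed, an alternative chosen after seeing the data, 10075 genes passed, of which 9261 had also passed before, and 212 of those changed sign. Genes are not independent replicates, so the intervals describe the genes of these libraries.

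**Figure D3:**
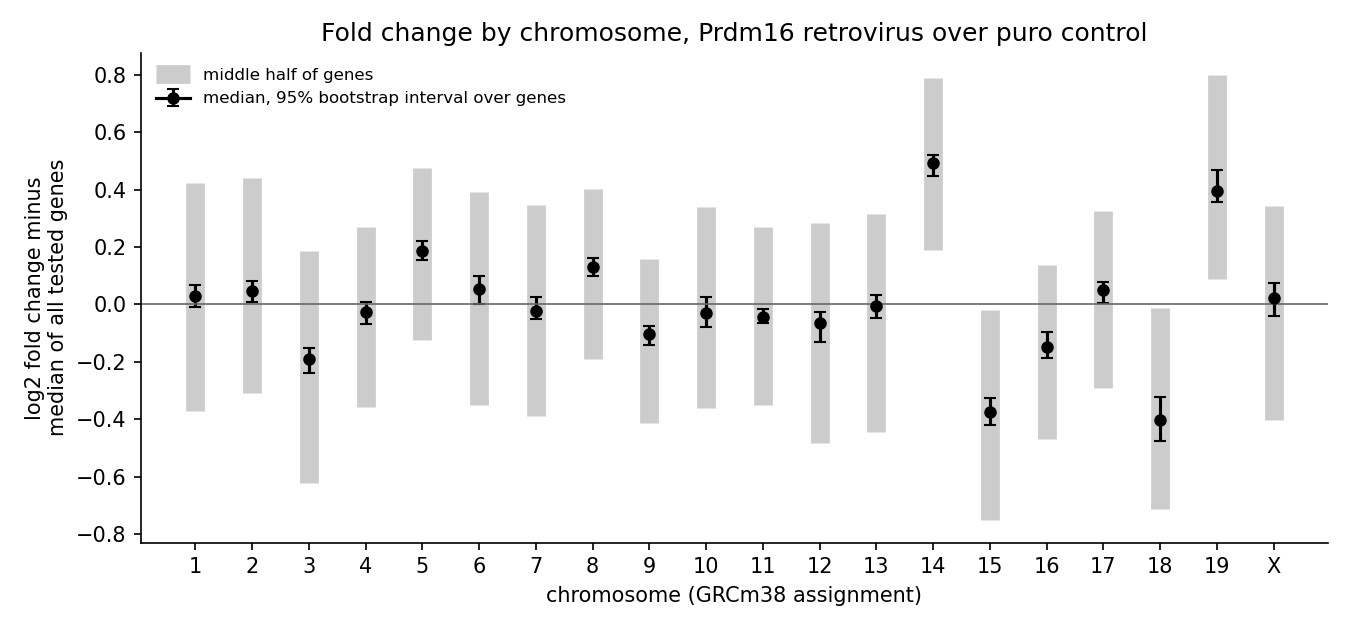
Median log2 fold change (Prdm16 over puro) of the tested genes on each chromosome minus the median of all tested genes, with a 95% bootstrap interval over genes, and a grey bar from the lower to the upper quartile. Chromosomes 14 and 19 lie above 0 and chromosomes 15 and 18 below it, with medians of 0.49, 0.40, −0.37 and −0.40.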

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

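Removal of chromosome medians and of the GC and length trend were the tests chosen only after the result was seen. The number of genes past the threshold lay between 9192 (adjusted p of 0.01) and 11149 (no low-count filter) over all settings, with 9839 by DESeq2 and 9884 to 10444 without 1 library. The log2 fold change of Prdm16 lay between 11.91 and 12.24 without 1 library. Of 132 named genes tested, none reversed its direction in any setting, and Cpt1b, Ppara and Tgfb1 changed side of the threshold in the settings given with their values. The number of lists called, 13 by camera with its preset correlation, was 0 with an estimated correlation, 25 with fry and 12 to 13 without 1 library. Fry does not compare a list with other genes, which by construction lets it call more lists in data where most genes changed. Directions reversed for 3 lists that camera never called. Wnt and Hedgehog genes did so on ranks (adjusted p = 0.97), with the replicate block (0.984), with GC and length removed (0.968) and without puro replicate 1, 2 or 3 (0.985 to 0.996; 0.913 to 0.996 without any 1 library). Endothelial markers did so without a low-count filter (0.993) and without 4 of the libraries (0.831 to 0.985; 0.774 to 0.985 without any 1 library), and pericyte markers with fry (2.39e-05, against 0.986 by camera with an estimated correlation) and without puro replicate 3 (0.996; 0.774 to 0.996 without any 1 library). The cause was not tested. Replicate numbers did not pair the libraries: deviations from the group means correlated at −0.16, 0.10 and −0.07 for the numbers 1, 2 and 3, against up to 0.25 for other pairs, and the replicate block gave 10089 genes and 14 lists, with macrophage markers added (adjusted p = 0.0471, against 0.31 with an estimated correlation and no block). At this depth Ucp1, Cidea, Lep and Retn, with at most 14 counts over a group, stayed below the main count filter, and their values without it were not examined.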

Other observations

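The gene groups and the tests of reassigned genes, chromosome parts, keratins, matrix spread, marker lists, splits and replicate spread were chosen only after the result was seen, as was the removal of GC and length trends and of chromosome medians, the limits of these removals having been written before their own outcome. Of 25 epithelial junction and splicing genes, picked after their values were seen so that the count restates the choice, 21 were higher, 3 lower and 1 not passing by edgeR's quasi-likelihood test. Among the higher ones Cdh1, Krt18, Esrp1, Epcam, Krt19, Mpzl2, Lsr and Fxyd3 are already given above under the fixed naming rule. The tight junction protein Ocln rose from 4 counts over the puro group to 1288 (log2 fold change 8.23 ± 0.23), the protease inhibitor Spint2 by 6.62 ± 0.10 and the desmosomal protein Dsp by 4.97 ± 0.12, whereas Cldn1, Pkp2 and Jup fell, at −2.87 ± 0.17, −0.59 ± 0.06 and −0.36 ± 0.05. Of 7 mesenchymal transcription factors, picked in the same way, 4 fell, with Snai2 at −1.48 ± 0.04, and 2 rose, with Zeb1 at 0.98 ± 0.04, while Prrx1 stayed at 244 ± 12.3 and 242 ± 6.35 CPM (SD, n = 3; adjusted p = 0.852).

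Members of the Hox clusters differed between the groups. Of the HoxA cluster 8 of 9 tested genes were higher and 1 did not pass, and all 3 tested genes of the HoxD cluster were higher, with Hoxd4 at 4.97 ± 0.21. Of the HoxC cluster 7 of 9 were lower and 2 did not pass, but it lies on chromosome 15, whose genes had a median of −0.37: with chromosome medians removed 6 were lower, 2 higher (Hoxc4 and Hoxc10, at 0.30 and 0.27) and 1, Hoxc5, did not pass. That removal left 7 of HoxA and 3 of HoxD higher. Of HoxB 5 of 9 were lower, 1 higher and 3 not passing, and 4 lower and 1 higher after the removal. Of 11 developmental genes, grouped after their values were seen and so no test of a theme, 6 rose and 5 fell. Among them Gata2, which rose, and Sox11, Wt1 and Tbx15, which fell, are already given above under the fixed naming rule. The stem cell factor Sox2 rose from 27 counts over the puro group to 4491 (log2 fold change 7.38 ± 0.11), the fetal growth factor Igf2 by 8.01 ± 0.15 and Gpc3 by 8.53 ± 0.22. Mecom, the nearest relative of Prdm16, fell from 42.4 ± 2.13 to 1.62 ± 0.424 CPM (SD, n = 3), a log2 fold change of −4.71 ± 0.12, and Gata3 fell by 2.89 ± 0.11.

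Genes of chromosomes 14 and 19 lay higher and those of 15 and 18 lower in the Prdm16 libraries, with smaller shifts of 3, 5, 8 and 16. A bias by GC content or transcript length is argued against, as 99.2% of the mean absolute median of chromosomes 14, 15, 18 and 19 was kept once that trend was removed. Chance assignment of genes is argued against too, the largest median of 1000 random reassignments being 0.115, against 0.49. A copy number difference between the cultures is a candidate explanation: with each of the 4 most shifted divided by gene order into 4 parts, 16 of 16 parts kept the chromosome's sign by at least 0.1, as did 15 of 16 parts of the 4 with smaller shifts. Regulation spread over whole chromosomes by Prdm16 was not tested and stays open, since no DNA was measured.

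Of the 16 mammary epithelial markers listed before the data 5 were higher in the Prdm16 libraries, 1 was lower and 10 had too few counts for a test. Krt5, Krt8, Krt14 and Krt17 summed to 12 counts over the 3 Prdm16 libraries. The exact 95% upper limit was 20.96, or 1.61% of the 1304 counts of Krt18. These counts argue only against admixed mammary epithelial cells that express these keratins abundantly. Krt19, a keratin left out of that sum, rose from 10 counts over the puro group to 706 over the Prdm16 group. Reads shared with keratin pseudogenes may be lost, so Krt8 may be undercounted. Admixed epithelial cells with few counted reads of these keratins stay open, and the test was chosen after the result was seen. A lower share of fibroblasts alone would move markers of the other cell types alike, if those cells were present. Lists of such markers with at least 2 tested members numbered 7, which leaves out lymphocytes. Of these, 5 held members both higher and lower by at least 1 on the log2 scale, and 4 of 6 without skeletal muscle. Tek at 3.08 ± 0.15 and Vwf at −2.57 ± 0.22 were an example. Some markers of these cell types, such as Cdh5 of endothelium and Sox10 of Schwann cells, had 0 counts in all libraries. The tested members may therefore come from the same cells, and the lists do not decide whether the share of fibroblasts changed. Dilution by a cell type with a profile of its own cannot be told apart from a change within the cells under Prdm16: the interquartile range of the log2 fold changes of matrix genes was 1.03, with a bootstrap interval over genes of 0.76 to 1.77, added after the value was seen, around the limit of 1. The marker lists were turned to after that spread had decided nothing, with their values and so the outcome known when the limit of 4 lists was set, and a count of the 5 matrix genes that rose was dropped because another cell type could bring those genes.

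Of the 13805 tested genes 10430 passed, with a biological coefficient of variation of 4.78% between replicates. Biases of GC content and length, and the shifts of whole chromosomes, are argued against as the whole cause, since 10453 and 10075 genes passed after their removal. The 10 splits of 6 libraries into 3 and 3 are too few for a share below 0.05: 1 of 10, the real one, gave 10430 genes, and the highest of the others gave 0 by edgeR at the adjusted threshold and 212 at an unadjusted p below 0.05. Whether the replicates of a group were drawn from 1 culture cannot be told apart. Their counts differed by more than sampling noise. A coefficient of variation of 4.78% did not reach the 20% set as the limit for separate cultures, and a spread below that limit does not show 1 culture. The test of this spread was chosen after the result was seen. Libraries of a group differed by at most 0.0616 in the medians of the most shifted chromosomes. The mean absolute median of these chromosomes between the groups was 0.416. If these shifts are of copy number, the libraries of a group share them and may stem from a shared cell population. That would not tell 1 culture from several of that population. If replicates of a group came from 1 culture or population, differences between 2 cultures, in their cells or chromosomes, may stand among the changes. The effect of Prdm16 stays open as a further explanation that these libraries cannot separate.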
